A study of Mus musculus with 8 samples.

How the data were processed

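RNA from 5 PPO1 mouse gliomas and 3 wild-type mouse cortices had been extracted as total RNA with a column kit, per the labels' protocols. Per the submitters' processing notes, the tools used were FastQC 0.11.7, Trim Galore 0.4.2, cutadapt 1.8.1, STAR 2.6.1e, featureCounts 1.6.2 and DESeq2, and the genome build was mm9. The notes give these names without roles, and the step that turned counts into FPKM is not given in the sources used here. The authors deposited the values as FPKM in 1 table of 24346 rows and 8 library columns, with gene symbols as the only identifiers. The smallest value above 0 is 1.74e-278, so some values are not whole multiples of what a read is worth and read counts could not be recovered. The fragment number of each library relative to cortex 1 was estimated from the most common ratio between libraries over low non-coding rows, as a rough guide to depth. The estimate assumes that many low rows do hold small multiples of the value of a fragment, which was not tested. It rests on 57 rows in the P120 tumour and up to 104 in the others. Of the rows, 27 had symbols turned into dates and were left out. Of the others, 23284 matched a gene name of the GENCODE M21 annotation and 1035 did not. That annotation was used for chromosome, gene order, gene type and transcript length. No coordinates are given, because its build differs from the one the submitters name.

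Widely used genes read near 0 in most of the table, so the rows that carry the level of their own gene were sought before genes were read, without regard to group. A path with 2 states (detection probability 0.65 or 0.07, switch probability 0.001) was fitted along the order of 17333 informative protein-coding genes, a gene being detected at a mean of at least 1 FPKM over all 8 libraries. Unnamed models and families with little use in brain, such as olfactory receptors, were left out of the path. It gave 11 stretches of at least 10 genes at chromosome starts and 3 in chromosome interiors. The 1030 protein-coding rows of the 11 stretches are the analysed genes, and 666 of them reached a mean of 1 FPKM. To test detection on genes that did not define the stretches, the path was also fitted without housekeeping rows and on the genes of each strand alone. Genes that share sequence with a pseudogene or close copy, such as Rpl35a, are uncertain because the notes do not say how shared reads were assigned, and overlapping or antisense genes cannot be told apart either.

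Libraries were grouped by their titles. A column was tied to a sample where its name matched that sample's title. The sample labelled P52 has no column of that name. The column naming day 53 matched no title and was kept as a PPO1 library with no stage or age, which leaves P68 as the only early tumour in the stage comparisons in place of the planned 2. Tests were made with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), over the 2379 rows with at least 1 FPKM in at least 2 of the 8 libraries, with a mean-dependent prior and Benjamini-Hochberg adjustment over all 2379 rows. The threshold was an adjusted p of 0.05. Differences are on the log2(FPKM + 1) scale and understate the change of low genes. Counts and named genes come from the 700 analysed genes among these rows. Over all 2379 rows the tests called 7 higher and 29 lower for tumour against cortex, and 323 and 402 for end stage against cortex. The 2-group fit of 5 tumours against 3 cortices had 6 residual degrees of freedom. The fit with each stage as a group had 3, and its spread rests on the cortices and the pair of end-stage tumours. The fit of a slope on age, per 30 days, had 4 and left out the unstaged tumour. On simulated values for 2379 genes with 200 changed, tumour against cortex recovered 42% of genes changed by 1 log2 unit and 83% of those changed by 2. End stage against cortex recovered 39% and 71%, and end stage against early 5% and 60%. In the same order, 6, 1 and 3 unchanged rows were called. The simulation gave each gene a single spread for all libraries and the same shift in every changed library. The deposited libraries need not share either, so these shares are a rough guide.

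The design, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes Pten and Trp53 in every library. For tumour against cortex it takes up to 8 genes in each direction with the largest difference past the threshold, no overlap between the groups and a mean of at least 5 FPKM in the higher group. For end stage against early it takes up to 5 in each direction. From each fixed list it takes up to 4 members, and it passes over unnamed models. Applied to all rows, the rule takes 13 genes for tumour against cortex, of which 4 lie outside the analysed genes and are not named. After the data were seen, it was restricted to analysed genes and extended to end stage against cortex. Of 442 entries in 31 fixed gene lists, 21 are analysed genes and no list holds 3, so the planned tests of whole lists and the exact permutation tests of list means were not run. Alternatives covered the pseudocount, the filter, scaling, the prior, library weights, a fold minimum, the stage structure and each library left out in turn. Those added after the data were seen covered the choice of stretches and rows, transcript length, the end-stage tumours and the place of the unstaged tumour. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.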

Results

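Bulk RNA sequencing of total RNA was used to profile gliomas of a mouse model named PPO1 and wild-type cerebral cortex. The series title ties the model to loss of the tumour suppressors Pten and Trp53, and the labels do not spell out the code. 5 tumour libraries and 3 cortex libraries were deposited as a table of FPKM values (fragments scaled to gene length and to library size) for 24346 rows. The cortices were taken at postnatal day 13 (P13). Tumours were labelled early at P52 and P68, late at P91 and end stage at P120 and P131. No column is named for the P52 tumour, and the column of the remaining tumour names day 53, which matches no sample label, so that tumour was used as a PPO1 library without a stage and is called the unstaged tumour. Age, genotype and tissue state change together between the groups, so a difference between tumour and cortex is also a difference between ages. The labels do not say whether the cortices came from separate animals, so p-values measure the spread between these samples, which may be technical for the cortices. FPKM sums ranged from 34613 in cortex 2 to 88807 in the P120 tumour. The files hold no read totals. From the most common ratio between libraries over low non-coding rows, cortex 2 and cortex 3 were estimated to hold 0.318 and 0.350 times the fragments of cortex 1. The tumours were estimated to hold 0.894 to 1.19 times. Rows above 0 numbered 8449 at P120, 11780 to 12253 in the other tumours, and 10296, 8305 and 8803 in cortex 1, 2 and 3. By that count P120 lay near cortex 2 and cortex 3, so its depth is uncertain and its values near 0 may partly reflect few reads.

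Pten and Trp53, the targeted genes, could not be checked. The Pten row read 0.00625 to 0.0268 FPKM in the cortices and 0.0108 to 0.0278 in the tumours. Trp53 read 6.20, 6.03 and 4.65 FPKM in the cortices, and among the tumours it read 12.5 in the unstaged, 7.96 at P68, 5.86 at P91, 0.447 at P120 and 3.74 at P131. Both rows lie in parts of the genome where most rows do not carry the level of the gene they name. Over all 8 libraries, a mean of at least 1 FPKM was reached by 24 of 257 rows of housekeeping families there (ribosomal, proteasomal and respiratory-chain genes among them). In 11 stretches at the starts of chromosomes 3, 5, 7, 8, 9, 12, 13, 16, 17, 18 and 19, 14 of 17 such rows reached it. These counts come from stretches found from detection of the other genes, with the housekeeping rows held out (Fisher's exact test, two-sided, p = 4.56e-11). The gene results are therefore limited to the 1030 protein-coding rows in these stretches, called analysed genes, of which 580 lie on chromosome 16 and 700 passed the filter on low values. Neither the Pten nor the Trp53 row is among them.

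**Figure D1:**
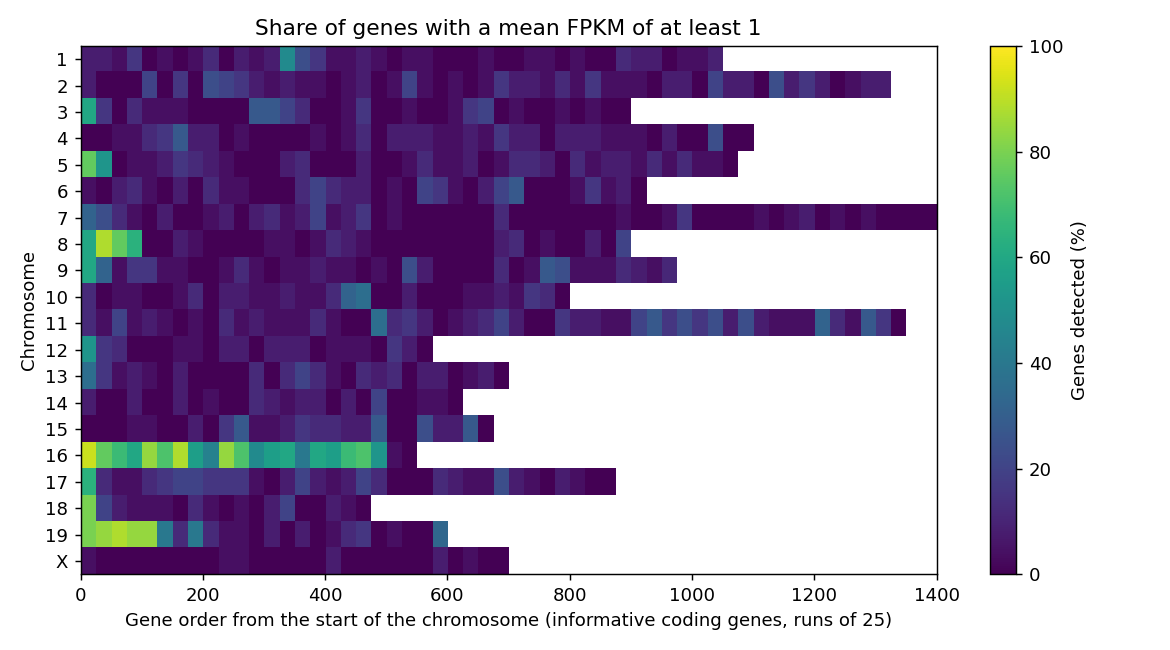
Share of informative protein-coding genes with a mean of at least 1 FPKM over the 8 libraries (colour, percent), in runs of 25 genes along each chromosome (rows; x axis, gene order). The analysed stretches lie at the starts of 11 chromosomes and cover most of chromosome 16; some runs elsewhere, such as 1 on chromosome 1 at 48% and 1 on chromosome 19 at 40%, exceed the first runs of chromosomes 7 (32%) and 13 (36%), and 3 interior stretches with 55 to 60% detected were left out. Of genes inside the analysed stretches, which were defined by this measure, 70.8% were detected, against 5.91% outside every stretch.

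PPO1 gliomas were compared with wild-type cortex, the comparison the design names. Cxadr, an adhesion protein of the immature nervous system and the coxsackievirus and adenovirus receptor, fell from 42.2 ± 2.84 FPKM in cortex (SD, n = 3) to 5.57 ± 2.69 in tumours (SD, n = 5). Dnmt3a, a de novo DNA methyltransferase, fell from 46.9 ± 2.14 to 7.84 ± 2.43 FPKM, and Cldn5, a tight-junction protein of brain endothelium, fell from 50.0 ± 10.4 to 12.3 ± 5.22. Arhgef10, a guanine nucleotide exchange factor for Rho, rose from 4.72 ± 0.441 to 13.0 ± 3.28 FPKM. Ltbp3, which binds latent TGF-beta, rose from 3.75 ± 0.0236 to 8.87 ± 1.52 FPKM. In each of these genes the 5 tumours lay on one side of the 3 cortices, which the rule for named genes requires. On the log2(FPKM + 1) scale, where the change of low genes is understated, the difference was -2.83 for Cxadr (SE 0.372, adjusted p = 0.0146), -2.49 for Dnmt3a (SE 0.281, adjusted p = 0.00714) and -1.997 for Cldn5 (SE 0.324, adjusted p = 0.0258). It was 1.26 for Arhgef10 (SE 0.228, adjusted p = 0.0401) and 1.04 for Ltbp3 (SE 0.182, adjusted p = 0.0364). Also lower in tumours were Bdh1, a ketone-body dehydrogenase (-1.79), the unconventional myosin Myo16 (-1.75), the sterol reductase Tm7sf2 (-1.69), Ehbp1l1 (-1.66) and Ypel1 (-1.03). Their adjusted p-values ran from 0.00487 for Myo16 to 0.0401 for Ypel1. Arhgef10 and Myo16 lie on chromosome 8, Dnmt3a on chromosome 12, Cxadr, Cldn5, Bdh1 and Ypel1 on chromosome 16, and Ltbp3, Tm7sf2 and Ehbp1l1 on chromosome 19. Apod, a lipocalin of oligodendrocytes, had the largest difference of the fixed cell-type genes at 3.82 (SE 0.819) without passing the threshold (adjusted p = 0.0687); it read 5.44 ± 1.05 FPKM in cortex and 18.0 to 215 FPKM in the tumours. In all, 2 analysed genes were higher and 12 lower in tumours by limma. Scaling to a common sum, which also made the pseudocount smaller relative to the values, gave 0 higher and 2 lower. A pseudocount of 0.1 without scaling gave 0 and 3, and removal of the 10 most abundant rows gave 3 and 24. The balance was even in the fit by stage (49 and 49) and with library weights (126 and 126). It leaned higher with late and end-stage tumours only (47 and 38). The total of 14 became 0, 0 and 1 without cortex 1, 2 and 3, and 46, 5, 7, 90 and 6 without the unstaged, P68, P91, P120 and P131 tumour.

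**Figure D2:**
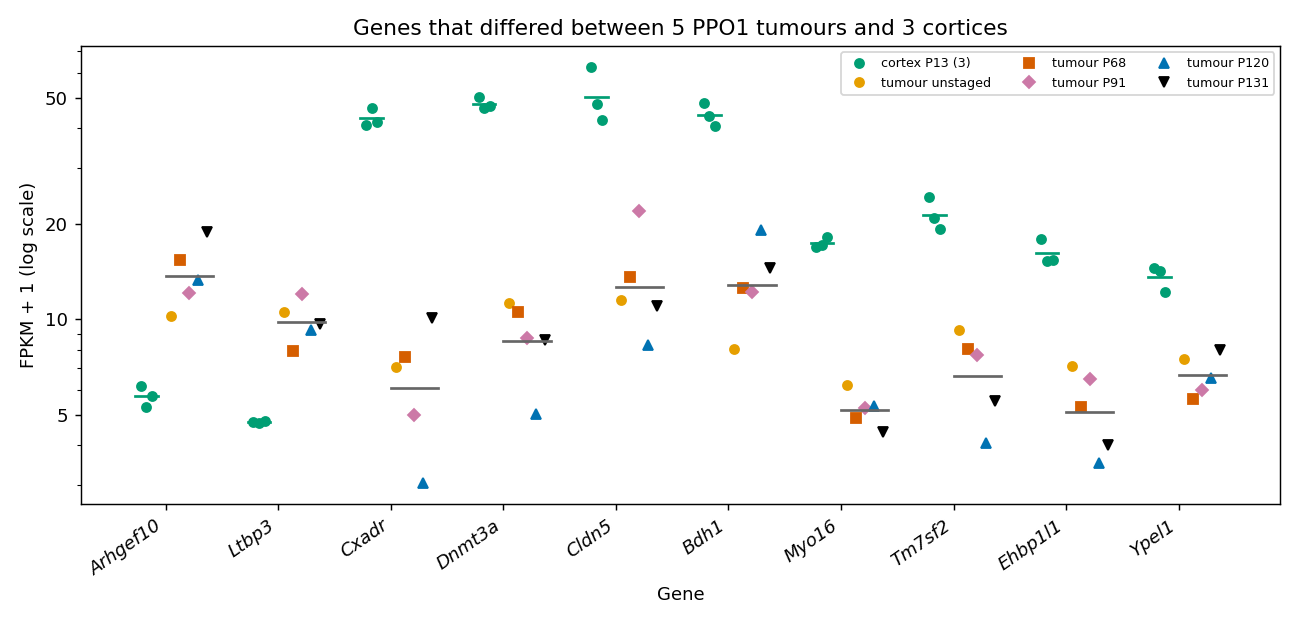
FPKM + 1 (log axis) of the 10 named genes in each library, with 3 cortices (green circles) to the left and 5 tumours to the right for every gene; lines mark the group means on the log scale. Arhgef10 and Ltbp3 lie higher in all 5 tumours, and the other 8 genes lie lower. The rule for named genes admits only genes without overlap between the groups.

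End-stage tumours were compared with cortex to resolve the main comparison by stage. Olig2 and Olig1, transcription factors of the oligodendrocyte lineage, rose: Olig2 went from 17.1 ± 1.49 FPKM in cortex (SD, n = 3) to 135 ± 47.9 in end-stage tumours (SD, n = 2), and Olig1 from 72.3 ± 5.41 to 551 ± 415. Of the 4 analysed members of the neuronal lists, 3 fell and Gap43 did not pass; the other members were not analysed. Stmn2, a microtubule regulator of growing neurons, went from 558 ± 37.5 to 28.4 ± 32.1 FPKM, the neuropeptide gene Sst from 178 ± 7.91 to 23.2 ± 24.9, and the NMDA receptor subunit gene Grin2a from 6.28 ± 1.01 to 0.545 ± 0.715. The log2 differences were 2.87 for Olig2 (SE 0.277, adjusted p = 0.0141), 2.67 for Olig1 (SE 0.553, adjusted p = 0.0310), -4.90 for Stmn2 (SE 0.920, adjusted p = 0.0259), -3.43 for Sst (SE 0.826, adjusted p = 0.0407) and -2.31 for Grin2a (SE 0.346, adjusted p = 0.0185). Among genes named by the rule, the largest rises were in Rtp4, an interferon-inducible gene, at 4.34 (SE 0.389, adjusted p = 0.0141) and Apod at 3.76 (SE 0.634, adjusted p = 0.0220). Besides Olig2 and Olig1, they were followed by Cebpd, a transcription factor of acute-phase responses (3.06), the semaphorin Sema3d (2.87), the ribosomal protein gene Rpl35a (2.73) and Litaf (2.54). Besides Stmn2 and Sst, the deepest falls were in Sptbn2, a beta-III spectrin of neurons (-4.30), the metabotropic glutamate receptor gene Grm3 (-3.41), the neuronal protein kinase C gene Prkcg (-3.34), Plcxd2 (-3.27), Cxadr (-2.96) and the postsynaptic scaffold gene Dlgap2 (-2.94). Their adjusted p-values ran from 0.0131 for Sema3d to 0.0341 for Rpl35a. The type IV collagen genes Col4a1 and Col4a2 were lower too, by -1.90 (adjusted p = 0.0295) and -2.33 (adjusted p = 0.0217). Of the 2 endothelial list members, Cldn5 fell (-2.39, adjusted p = 0.0145) and Abcb1a did not pass (-1.22, adjusted p = 0.146, and 0.0761 adjusted over the list alone). The 2 end-stage libraries differed in depth of change, with Stmn2 at 5.68 FPKM at P120 and 51.1 at P131, and Grin2a at 0.0390 and 1.05. The pair correlated at r = 0.864 across analysed genes, and the cortices with one another at 0.993 to 0.995. The fit gave all groups a common spread. The errors above may therefore understate the spread between end-stage tumours and make the adjusted p-values too small. Across analysed genes, the P120 tumour correlated with the cortex mean at r = 0.611 and the P131 tumour at 0.800, against 0.877 to 0.943 in the other 3 tumours. Short transcripts were higher and long ones lower at P120, with a median log2 ratio to cortex of 0.66 in the shortest 20% of genes and -0.74 in the longest 20%; the same medians were 0.19 and -0.09 at P91 and 0.23 and -0.08 at P131. In all, 131 analysed genes were higher and 116 lower by limma. After scaling to a common sum, which moved the median gene by -1.01, the split was 25 and 229. The row Mir3572 made up 57.9% of the sum at P120 and 28.1% at P131, against 16.1 to 21.7% in the cortices. Scaling to the sum therefore lowers the other genes at end stage. Without the 10 most abundant rows the median moved by -0.11 and the split was 92 and 127. With no filter it was 42 and 25. With library weights it was 1 and 0, so at most 1 of the genes named here kept its call there. The total of 247 became 0 without any of cortex 1, 2 or 3 (237 to 248 genes at an unadjusted p under 0.05), 435 without the P120 tumour and 548 without the P131 tumour; in these last fits the lone end-stage tumour is assumed to vary like the cortices.

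**Figure D3:**
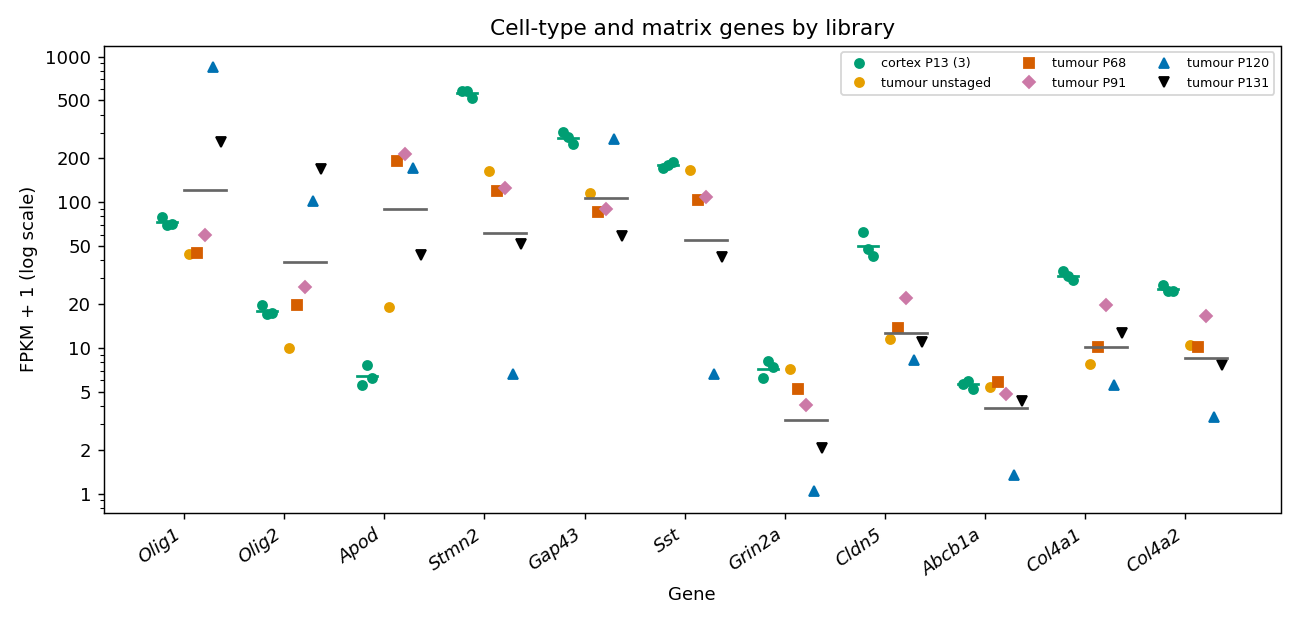
FPKM + 1 (log axis) of 11 genes from the cell-type and matrix lists in each library, with 3 cortices (green circles) to the left and 5 tumours to the right for every gene; lines mark the group means on the log scale. Olig1 and Olig2 lie above the cortices in the P120 and P131 tumours, and Stmn2, Sst and Grin2a lie lowest in the same 2 tumours.

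The early tumour, the P68 library alone, was compared with cortex in the same fit. Sec14l5, a gene of the SEC14 lipid-transfer family, rose from 0.130 ± 0.0572 FPKM in cortex (SD, n = 3) to 2.38 at P68. Its log2 difference was 1.58, and it lost its call in 9 of 21 alternatives. It was the only analysed gene past the threshold by limma and is named although it was chosen after its values were seen. Apod read 191 FPKM at P68 against 5.44 ± 1.05 in cortex (4.91, SE 0.802, adjusted p = 0.135), and Dnmt3a read 9.55 against 46.9 ± 2.14 (-2.18, SE 0.349, adjusted p = 0.134). Olig2 read 18.8 FPKM, close to the 17.1 ± 1.49 of cortex. No analysed gene was called lower by limma, and 58 were lower at an unadjusted p under 0.05. This split of 1 higher and 0 lower turned to 0 and 5 with a filter of 5 FPKM, 0 and 2 without a variance trend, 87 and 118 with library weights and 33 and 17 with no filter. With a single early tumour its spread is taken from the other groups, and without the P120 or P131 tumour from the cortices alone. The total of 1 became 0 without any of cortex 1, 2 or 3, and 230 and 229 without the P120 and P131 tumour.

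End-stage tumours were compared with the early tumour, and a slope on age was fitted over the 4 staged tumours, to follow change with stage. B3gnt5, a glycosyltransferase of glycolipid synthesis, rose from 0.381 FPKM at P68 to 7.83 at P120 and 6.47 at P131, a log2 difference of 2.56 (SE 0.218, adjusted p = 0.0241). The spread behind this error comes from the cortices and the end-stage pair, since the early group is 1 library, and the call was lost in 8 of 22 alternatives (adjusted p from 0.00239 to 0.197). Sema3d, Dbf4 and Shcbp1 rose with age. Dbf4, the activator of the Cdc7 kinase at replication origins, read 1.05, 3.11, 8.11 and 12.4 FPKM at P68, P91, P120 and P131, a slope of 1.27 log2 units per 30 days (SE 0.102, adjusted p = 0.0355). Sema3d read 2.82, 9.77, 17.3 and 26.5 FPKM (slope 1.27, SE 0.146, adjusted p = 0.0487), and Shcbp1, which is expressed in dividing cells, read 0.350, 2.03, 5.32 and 6.62 FPKM (slope 1.19, SE 0.134, adjusted p = 0.0487). These 3 genes were named after their values were seen, since the rule for named genes does not cover the slope. Their errors draw in part on the spread of the cortices, which may be technical. Their calls were lost in 9 (Dbf4), 12 (Sema3d) and 14 (Shcbp1) of 23 alternatives, with adjusted p up to 0.235, 0.416 and 0.463. Olig1 and Olig2 did not pass over all genes tested: Olig2 differed between end stage and P68 by 2.73 (SE 0.371, adjusted p = 0.0824) and Olig1 by 3.39 (SE 0.742, adjusted p = 0.149). No analysed gene was called lower by limma at end stage than at P68 or with age, against 79 and 58 at an unadjusted p under 0.05. With the unstaged tumour taken as the P52 early tumour, 91 genes were higher and 82 lower at end stage, and 50 rose and 20 fell with age; with no filter, 30 were higher and 17 lower at end stage. The end-stage count of 1 became 0 without any of cortex 1, 2 or 3, 245 without the P120 tumour and 487 without the P131 tumour; these last fits set 1 tumour against 1, with the spread of the cortices alone, which may be technical. The slope count of 3 became 0 without any of cortex 1, 2 or 3 or the P68 tumour, 114 without the P120 tumour and 372 without the P131 tumour.

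Of the 31 gene lists fixed for cell types and pathways, 16 had a member among the analysed genes and none had more than 2, so no list as a whole was tested. Of these 21 members, 17 passed the filter. Adjustment over the list alone was made within each list, over its 1 or 2 tested members. For a list with 1 tested member it is the unadjusted p, and no such value is adjusted over the 17 members. Against cortex, 3 rose at end stage (Olig1, Olig2 and Apod) and 7 fell (Stmn2, Sst, Grin2a, Cldn5, Col4a1, Col4a2 and Npas4, an activity-induced transcription factor). With no filter, only Olig2 and Cldn5 of these kept their calls. With library weights 1 analysed gene in all was called at end stage, so at most 1 of these calls held. Adjusted over the list alone, the counts in the reported fit were 3 and 8, the added gene being Pcp2. Over all 5 tumours, 0 rose and 1 fell (Cldn5) by limma; adjusted over the list alone, 1 rose (Apod) and 5 fell (Stmn2, Gap43, Cldn5, Col4a1 and Col4a2). Between end stage and P68, 0 passed over all genes, and adjusted over the list alone 2 were higher (Olig1 and Olig2) and 2 lower (Grin2a and Clic6). For the P68 tumour against cortex, 0 passed over all genes, and adjusted over the list alone 2 were higher (Apod and Clic6) and 4 lower (Cldn5, Col4a1, Col4a2 and Npas4). On the slope with age, 0 passed over all genes, and adjusted over the list alone 2 were higher (Olig1 and Olig2) and 2 lower (Grin2a and Npas4). Gap43, a growth-cone protein gene, read 278 ± 26.5 FPKM in cortex, 272 at P120 and 57.7 to 115 in the other tumours. The Notch target genes Hes1 and Hey1 and the Hippo effector gene Yap1 did not pass against cortex in the reported fits: Hes1 read 4.01 ± 0.671 FPKM in cortex and 6.99 ± 3.31 in tumours, Hey1 21.7 ± 1.14 and 19.5 ± 6.50, and Yap1 5.07 ± 0.317 and 4.60 ± 2.54. Hes1 was called higher over all tumours with library weights (0.81, adjusted p = 0.0389), and at end stage without the P131 tumour (0.78, adjusted p = 0.0325). At end stage against cortex, Hey1 and Yap1 were called higher (0.45 and 0.50) without the P120 tumour and lower (-0.77 and -1.68) without the P131 tumour. Abcb1a, a drug-efflux transporter gene of brain endothelium, read 4.63 ± 0.340 FPKM in cortex and 3.35 ± 1.77 in tumours. Cdk6, Igf2bp2, Myh11 and Ciita stayed below the filter, with cortex means of 0.954, 0.382, 0.411 and 0.0968 FPKM. The other 15 lists, among them those for proliferation, microglia, astrocytes, p53 targets and hypoxia, had no analysed member.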

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

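The tests of genome coordinates, depth, strand, the shared end stage, the length correction, cortical cells, age and other splits were specified after the result they bear on was seen, and the test of transcript length among genes stable at P131 before its result was known.

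Rows of widely used genes near 0 are the first pattern. Low sequencing depth is argued against by housekeeping genes held out of the search for stretches, 82.4% of which were detected inside and 9.34% outside in the same libraries. Counting on the wrong strand would act on the whole genome alike, and of minus-strand genes 66.4% were detected inside stretches found from plus-strand genes alone against 6.13% outside. A candidate explanation is that gene models and alignments were in different genome coordinates, so that rows carry their own reads only up to the first shift of a chromosome. When the path gave chromosome starts no preference, 10 of 14 stretches still began within the first 3 informative genes, as a shift would need. The 3 interior stretches, on chromosomes 1, 6 and 10 with 55 to 60% detected, are not accounted for by loss after the first shift. No biological explanation was tested, and the build of the gene models stays open.

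The P120 tumour is the second pattern. Its log2 ratio to cortex changed by -0.44 per doubling of transcript length (95% bootstrap interval over genes -0.56 to -0.33). The P131 tumour of the same stage had -0.0899 (-0.162 to -0.0135) and the late P91 tumour -0.0956 (-0.150 to -0.0428), both smaller and of the same sign. Each interval covers the genes of a single library and not the spread between animals. The intervals of the cortices also kept a single sign, with slopes of -0.0341, 0.0101 and 0.0239 in cortex 1, 2 and 3. A slope of the P120 size was absent from the only other end-stage library, which cannot exclude an end-stage effect that varies between tumours. Loss of the genes that also fell at P131 is argued against by 174 genes within 0.3 log2 units of cortex at P131, where the P120 slope was -0.47 (-0.61 to -0.34). The number of end-stage calls did not fall with the length trend removed, at 259 genes against 247 before. Whether these were the same genes was not compared, so the trend may still lie behind part of the 247 calls. RNA breakage, size selection or the state of the tumours may each underlie the trend and its excess at P120, and no value separates them.

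Genes lower in all tumours than in cortex are the third pattern. 2 of the 56 splits of the 8 libraries into 5 and 3 gave as many calls as the 14 of the real split, which excludes chance at 0.05 only if the libraries are exchangeable; the cortices may be technical replicates, and without cortex 1, 2 or 3 the count was 0, 0 and 1. The highest other split, with the P91, P120 and P131 tumours as the group of 3, gave 82 genes, several times the real count, which points to a structure of the samples; these 3 are the later tumours and also those with the steepest length trends, and stage and length were not separated. Fewer cortical cells in the tumour samples may lower such genes. The median of the 12 called genes was set against that of the neuronal list members (Stmn2, Gap43, Sst and Grin2a). It lay lower by 0.73, 0.40 and 0.18 log2 units in the unstaged, P68 and P91 tumours. Only the first gap exceeded the spread of those members (0.62, 0.62 and 0.44). That spread is between single genes and is not the error of a median. At P120 and P131 the order turned, with called genes at -1.83 and -1.78 and neuronal members at -3.78 and -2.17. The called genes passed a test over these same tumours that favours an even fall in all 5, so their steadier course may come from how they were called. With 4 neuronal genes besides, fewer cells cannot be told apart from a change within cells. Age of the animals stays open and untested, because 0 of the 3 cortices were older than P13.

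The estimated relative fragment number of the P120 tumour, 0.894, lay far from the 1.13 to 1.19 of the other 4 tumours, its gap being 0.797 of the whole range. Abcb1a at P120, 0.345 FPKM, lay far from the 3.36 to 4.81 FPKM of the other tumours. Its gap was 0.804 of the range on the log2(FPKM + 1) scale, and the share would differ on the FPKM scale. These were 2 of 49 measures examined over the 5 tumours, and chance alone flags about 1 in 20. Whether few reads at P120 lowered Abcb1a there was not tested. B3gnt5 differed between the end-stage and the early effect by 2.56 log2 units, as tested in the stage comparison. Among rows outside the analysed genes, Mir3572 read 51448 FPKM in the P120 tumour, which is 57.9% of that library's FPKM sum, against 18464 FPKM (28.1%) at P131, 9930 at P91, 5852 and 6585 in the unstaged and P68 tumours, and 6138 to 8534 FPKM in the cortices.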

How the results depend on the processing

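The alternatives on rows, stretches, transcript length, omission of the end-stage tumours and the place of the unstaged tumour were chosen after the data were seen. Counts of calls moved by over 1.5 times in most alternatives, and the cause was not tested except where stated. For tumour against cortex (14 calls), the total was 3 with a pseudocount of 0.1, 4 with no filter, 2 after scaling to TPM, 24 with median-of-ratios scaling, 40 with quantile normalization, 27 without the 10 most abundant rows, 252 with library weights, 98 in the fit by stage, 85 with late and end-stage tumours only, 154 without end-stage tumours and 32 in a fit of analysed genes only. For end stage against early (1 call), the totals in the first 5 of these settings were 0, 47, 0, 5 and 10; they were 2 with a filter of 5 FPKM or no variance trend, 7 in analysed genes only, 4 with the length trend removed and 173 with the unstaged tumour taken as early. For early against cortex (1 call), they were 0, 50, 0, 2 and 9, then 5 with the filter of 5 FPKM, 2 with no variance trend, 205 with library weights, 0 in analysed genes only or with the length trend removed, and 11 with the unstaged tumour as early. For end stage against cortex (247 calls), the total moved to 67 with no filter and 1 with library weights, and lay within 1.5 times of 247 in the other scalings and settings that kept all libraries. For the slope on age (3 calls), it was 1 with a pseudocount of 0.1, no variance trend or the length trend removed, 0 with no filter, a filter of 5 FPKM, TPM, median-of-ratios scaling or library weights, 7 in analysed genes only and 70 with the unstaged tumour included. Higher and lower calls split as 4 and 1 (median-of-ratios) and 8 and 2 (quantile) for end stage against early, and as 1 and 1 and 2 and 7 for early against cortex.

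Leaving out 1 library gave 0 to 90 calls for tumour against cortex, 0 to 487 for end stage against early, 0 to 230 for early against cortex, 0 to 548 for end stage against cortex and 0 to 372 for the slope. In analysed genes only, leaving out cortex 1, 2 or 3 gave 45, 93 and 37 calls for end stage against cortex and 4, 2 and 4 for tumour against cortex. Alternatives with 0 calls still had 95 to 100, 90 to 181, 48 to 121, 237 to 248 and 54 to 179 genes at an unadjusted p under 0.05 by limma, in the order of the comparisons above. Neither comparison with the early tumour could be fitted without the P68 tumour. The pseudocount of 1 was kept on the larger TPM values and so weighed less there. Scaling to TPM moved the median gene by -0.53, -0.81, -0.22, -1.01 and -0.42 in the same order, median-of-ratios scaling by 0.20 for end stage against early and 0.18 for end stage against cortex, and removal of the abundant rows by -0.14, -0.13 and -0.11 for tumour, early and end stage against cortex. None of 44 called results of named genes turned direction in any alternative run for it. This is a weak check, because most alternatives could not turn many of them. Genes named by the rule had no overlap between the groups, so leaving out a library could not change their direction. Settings of the filter, the variance trend, the fold minimum and the rows leave the difference itself unchanged. Dnmt3a kept its call for tumour against cortex in 23 of 28 alternatives, Myo16 in 24 and Ypel1 in 14. Olig2 kept its end-stage call in 22 of 26, with adjusted p from 0.00152 to 0.0997, and Sst in 17. Hey1 (0.45) and Yap1 (0.50) turned from lower without a call to higher with a call at end stage when the P120 tumour was left out; over the libraries left out in turn their lowest values were -0.77 and -1.68, without the P131 tumour. Without read totals, the depth limit of low genes is unknown.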

Other observations

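The genes in the next paragraph were chosen by hand after their values were seen and stand for no gene group.

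Some genes called at end stage against cortex lie outside the rule for names. Cdca5, the cohesin regulator sororin, read 0.451 ± 0.0953 FPKM in cortex (SD, n = 3), 0.141 at P68, 1.56 at P91, 8.13 at P120 and 3.32 at P131 (2.12, adjusted p = 0.0217). Parp9, an interferon-inducible gene, read 0.434 ± 0.0814 FPKM in cortex and 7.33 and 4.59 at end stage (2.25, adjusted p = 0.0141). Tcirg1, a subunit gene of the vacuolar proton pump, read 4.06 ± 0.336 FPKM in cortex and 23.0 and 17.4 at end stage (2.05, adjusted p = 0.0141). The coagulation cofactor gene Pros1 and the cytokine gene Clcf1 were at 7.74 and 8.97 FPKM at P91 already, against 1.09 ± 0.0718 and 0.366 ± 0.118 in cortex. The splicing factor gene Rbfox1 read 45.0 ± 2.26 FPKM in cortex, 41.8 in the unstaged tumour, 39.0 at P68, 39.5 at P91, 2.62 at P120 and 14.2 at P131 (-2.63, adjusted p = 0.0419). Rtn4r, the Nogo receptor gene, had a like course, with 35.3 ± 1.77 FPKM in cortex, 24.5 to 32.3 in the unstaged, P68 and P91 tumours, and 2.18 and 8.71 at end stage (-2.71, adjusted p = 0.0260). Rasgrp2, a Rap exchange factor gene, was already at 9.63 FPKM at P68 and 3.92 at P91, against 25.6 ± 1.99 in cortex (end stage -2.80, adjusted p = 0.0131).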
